A study of Rattus norvegicus with 40 samples.

How the data were processed

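Total RNA from kidneys of male rats was labelled with Cy5 and hybridised to CodeLink rat arrays, per the labels. There were 40 arrays in 20 groups of strain and treatment. Each label named 2 animals, and whether their RNA was pooled is not given in the sources used here. Per the file headers, each deposited array file held a normalised intensity and a quality flag per probe. The scanner software and normalization steps are not given in the sources used here. From the values, each array had a median intensity of 1, and 9269 values were 0 or below, so background had been subtracted. The authors' deposited series tables held the same intensity values (largest difference 0 over 1337935 values compared), with values of 0 or below missing. They were used, without quantile normalization or floor, as an alternative. Of 780 pairs of arrays 0 held identical values.

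Intensities were quantile normalised between arrays, set to a floor of 0.38 (near the 1st percentile of good-flagged values) and taken to log2. The plan had named a normexp background correction with an offset of 50 as the first choice and the background-subtracted values with a floor as its alternative. That offset lies far above the median intensity of 1. The order was therefore swapped after the values were seen, and normexp with the floor as offset became the alternative. Of 33849 probes, 24993 had a good flag on both arrays of at least 1 group and a value in every group, and were tested. A gene with no good flag on 1 side is given as "at least N-fold", computed against the highest of the floor, the array's lowest good-flagged intensity and the probe's own value.

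Gene symbols came from the series' probe table and were updated through a RefSeq gene table of assembly GRCr8, used for names only. Of the probes 16753 had 1 symbol, 165 several genes and 16931 none.

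Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) to all 40 arrays with 1 mean per group and 20 residual degrees of freedom. Calls needed a Benjamini-Hochberg adjusted p under 0.05. Strain was SHRSP minus WKY averaged over the 4 vehicles, and a drug effect was drug minus vehicle averaged over the strains. The labels do not name the vehicle of each drug. It was taken from the scan session (Solvent A for candesartan, B for chlorothiazide, C for carvedilol, H2O for enalapril), and H2O was assumed for amlodipine and hydralazine. Slide series was read from the array titles. The comparisons limited to arrays that share session and slide series with their vehicle, and amlodipine minus hydralazine, were chosen after seeing the data.

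The 32 gene lists, with 1 probe per gene (the brightest with a value on every array, which for Havcr1 is GE13234), were tested with camera at a preset correlation of 0.01 and at an estimated one, adjusted over the lists of a comparison. Genes were named by a rule: the 8 highest and 8 lowest changes past the threshold with 1 symbol, up to 4 members of each list past it by smallest p, and a panel of drug target genes whatever their p. Other comparisons took the 5 smallest p. Lists, the alternatives below except where stated and this rule were written before the data were examined. Values of second probes, the genes followed by strain and probes GE21429 and GE14830 were chosen after their values were seen.

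The code was tested on simulated changes planted in 24319 probes. It recovered 67.2%, 95.5% and 100% of log2 changes of 0.5, 1 and 2 for candesartan, 29.9%, 79.1% and 98.5% for enalapril in SHRSP, and 91% at 0.5 for strain. Alternatives tried were normexp, median scaling, the authors' tables, no filter, probes with a good flag on all 40 arrays, session as a fixed or random block, eBayes with trend and robust, array weights, pooled vehicles, only the compared groups in the fit, and leaving out each array. Leaving out spots flagged POOR was added after seeing the data. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9 read the values and drew the plots.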

Results

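Gene expression was measured in kidneys of male rats at 16 weeks of age from the stroke-prone spontaneously hypertensive strain SHRSP/Izm and the normotensive strain WKY/Izm. Rats had received 1 of 6 antihypertensive drugs or 1 of 4 vehicles, and the question was how different drug classes change the kidney transcriptome. The drugs were enalapril (an angiotensin-converting enzyme inhibitor, 20 mg/kg/day), candesartan (an angiotensin receptor blocker, 5 mg/kg/day), chlorothiazide (a thiazide diuretic, 20 mg/kg/day), carvedilol (a blocker of beta and alpha-1 adrenergic receptors, 50 mg/kg/day), amlodipine (a calcium channel blocker, 20 mg/kg/day) and hydralazine (a direct vasodilator, 10 mg/kg/day). The 20 groups of strain and treatment had 2 CodeLink arrays each, 40 in all, and each label named 2 animals that differed between the arrays of a group. Between 59.3% and 72.6% of the probes on an array carried the scanner flag for a good signal, and 24993 probes were tested. Changes are log2 values ± standard errors from limma, with Benjamini-Hochberg adjusted p. With 2 arrays per group, the number of arrays limits the precision.

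The strains separated on the first principal component, which held 32.8% of the variance and of which strain accounted for 94.5%. The second held 18.6%, and scan session with slide series accounted for 85.3% of it. Most treatments lay within a single session and slide series, so this share can also hold differences between treatments. Replicates on the same batch of session and slides differed by a median root mean square of 0.23 on the log2 scale (17 pairs), those on different batches by 0.40 (3 pairs). Candesartan, chlorothiazide and carvedilol shared session and slide series with the vehicle taken as theirs in both strains, and enalapril did so in SHRSP. These are called matched comparisons. Amlodipine, hydralazine and, in WKY, enalapril did not share slide series with H2O.

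**Figure D1:**
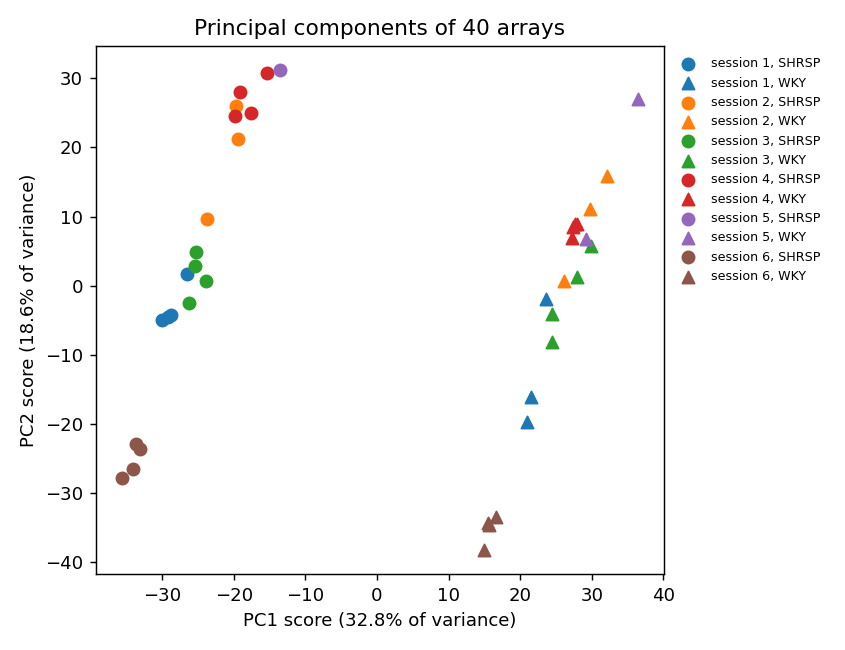
Scores of the 40 arrays on the first and second principal components of the log2 intensities. Circles are SHRSP arrays, triangles WKY arrays, and colours the 6 scan sessions. The strains part along the first component, which holds 32.8% of the variance, and sessions part along the second, which holds 18.6%.

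Untreated SHRSP kidneys were compared with WKY kidneys (8 vehicle arrays against 8, averaged over the 4 vehicles). Single genes of injury, immunity and smooth muscle differed, while camera with an estimated correlation called 0 of 32 lists (5 at an unadjusted p under 0.05). Among genes of tubular injury, clusterin (Clu) rose by 1.15 ± 0.09 and keratin 19 (Krt19) by 0.55 ± 0.06, and of 22 measured members 13 rose, 3 fell and 6 did not pass (adjusted over the list alone, 13 rose and 3 fell). Of 25 genes of antigen presentation and interferon response, 10 rose and 15 did not pass, among them the MHC class II genes Cd74 (0.77 ± 0.06) and RT1-Da (0.72 ± 0.05). Lysozyme (Lyz2) rose by 1.07 ± 0.07 and the Fc receptor Fcgr3a by 0.99 ± 0.06, and of 37 macrophage and inflammation genes 16 rose, 4 fell and 17 did not pass. Of 11 smooth muscle and pericyte genes 5 rose, including the contractile genes Tagln (0.80 ± 0.11), Cnn1 (0.58 ± 0.07) and Myh11 (0.34 ± 0.04), and 1 fell. Extracellular matrix genes went the same way, with 18 of 38 higher and 3 lower. Of 21 cholesterol synthesis genes, each on the probe used for its list, 5 fell and 16 did not pass, while a second probe of Stard4 rose by 0.22. The panel genes were Slc12a3, the thiazide-sensitive sodium chloride cotransporter, at 0.38 ± 0.05 and 0.19 on its other probe, Agtr1b at 0.21 ± 0.05, Agtr1a at -0.17 ± 0.05 and the calcium channel gene Cacna1c at -0.27 ± 0.09. Ace (-0.02 and -0.12 on its probes) and Agt (0.03) did not pass.

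In all, 5453 probes differed between the strains, 2786 higher and 2667 lower in SHRSP (3574 among the 14054 probes with a good flag on all 40 arrays). Large increases among named genes included Plpp5 (at least 32.5-fold, not well above background in WKY), Mob4 (3.90) and Spg11 (3.88). Large decreases included Tgm2 (transglutaminase 2, at least 79.4-fold lower) and Rrp1 (-5.13, a good flag on 5 of 8 SHRSP arrays). The cathepsin Ctsh fell to the floor on all 8 SHRSP arrays, so the size of its decrease was not measured. Of 33 named genes that differed by at least 8-fold, 14 had another probe, and the median ratio of the other probes' difference to that of the first was 0.03. Squalene synthase (Fdft1) was -4.99 on its first probe and -0.31 on its other one, and Tgm2, lower on its first probe, was 0.46 on its other one. Havcr1 (kidney injury molecule 1, shed by damaged proximal tubules) was 3.13 ± 0.30 on probe GE1278517 and -0.74 on probe GE13234, both past the threshold (adjusted p = 2.5e-08 and 0.0102), so its strain direction depends on the probe. Of 32 gene lists, camera with a preset correlation of 0.01 called 10 for strain. With an estimated correlation adjusted p was 0.34 for injury, 0.233 for antigen presentation, 0.372 for macrophage, 0.139 for smooth muscle, 0.251 for matrix and 0.251 for cholesterol synthesis genes.

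Within SHRSP, enalapril (2 arrays against 2 with H2O) lowered genes of tubular injury, matrix and proliferation. Havcr1 fell by 4.61 ± 0.60 (adjusted p = 0.000614) on one probe and by 2.77 on the other (adjusted p = 0.0011). Lcn2, the neutrophil gelatinase-associated lipocalin, fell by 2.08 ± 0.37, osteopontin (Spp1) by 1.77 ± 0.28 and Gpnmb by 1.87 ± 0.25. Of the 22 measured injury genes 8 fell and 14 did not pass (adjusted over the list alone, 13 fell and 1 rose). Collagen Col1a1 fell by 1.30 ± 0.20, the metalloproteinase inhibitor Timp1 by 1.27 ± 0.18, periostin (Postn) by 1.53 ± 0.26 and tenascin C (Tnc) by 0.71 ± 0.12, and 7 of 38 matrix genes fell with none rising, each on the probe used for its list, on which Col1a1 did not pass (-0.30, adjusted p = 0.798). Of 33 cell cycle genes 3 fell: Top2a (-1.01 ± 0.22), Cdk1 (-0.86 ± 0.16) and Mcm5, which on another probe than the list's was at least 1.94-fold lower and not well above background with enalapril. Calbindin (Calb1), a calcium-binding protein of the distal tubule, fell by 0.70 ± 0.14. The kallikrein-family gene Klk1c4 rose by 0.83 ± 0.19. The injury (adjusted p = 0.0113), matrix (0.00179), smooth muscle (0.00781) and cell cycle (0.00781) lists fell by camera with an estimated correlation. Proximal tubule, macrophage, antigen presentation, immediate early and gluconeogenesis lists were called only with the preset one (adjusted p with an estimated correlation = 0.0974, 0.14, 0.0974, 0.452 and 0.104), and 3 of these were higher.

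By limma 245 probes passed for enalapril in SHRSP, 53 up and 192 down. The H2O arrays of SHRSP spread widely for these genes (SD 1.05 for Havcr1 and 0.99 for Lcn2, n = 2), and of 33 named genes 5 kept their call whichever of the 4 arrays was left out: Havcr1, Gpnmb, Timp1, Col1a1 (on the probe called, not its list's) and Col15a1. Over both strains (4 arrays against 4) enalapril gave 523 probes, 299 up and 224 down. The count was 206 without SHRSP H2O replicate 2, 44 with array weights, 892 with session as a fixed block and 1560 with vehicles pooled, and with only the compared groups in the fit limma called 0 (3057 at an unadjusted p under 0.05). The share of calls that were higher was 57.2%, but 77.9% with median scaling and 82.7% with the authors' tables. Of the lists 4 passed with the preset correlation and 0 with an estimated one (3 at an unadjusted p under 0.05).

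Candesartan (4 arrays against 4 with Solvent A, both strains) lowered Calb1 by 0.80 ± 0.10 (adjusted p = 0.000282) and the matrix-degrading Mmp9 by 1.06 ± 0.13 (0.000282). Tenomodulin (Tnmd) fell by 0.81 ± 0.12, the neuropeptide Y receptor Npy1r by 0.48 ± 0.07 and Olfml2b by 0.44 ± 0.08. Klk1c4 rose by 0.76 ± 0.13 (adjusted p = 0.0268) and Pak6 by 0.23 ± 0.04. The unnamed probe GE21429 rose by 3.39 ± 0.20. Matrix genes shifted down as a list (adjusted p = 0.00129 with an estimated correlation), with Mmp9 the 1 of 38 past the threshold and 5 lower when adjusted over the list alone, and so did the 33 cell cycle genes (0.00648), none of them past the threshold over all probes. Injury, macrophage, antigen presentation and immediate early genes were lower with the preset correlation only (adjusted p with an estimated correlation = 0.24, 0.376, 0.376 and 0.452). The angiotensin receptor genes Agtr1a (0.13 ± 0.07) and Agtr1b (-0.08 ± 0.07), Ace (-0.07 and 0.10 on its probes) and Agt (0.15 ± 0.18) did not pass. Limma called 13 probes, 6 up and 7 down. Ddx24 was called up, but in WKY it had a single Solvent A value, at the floor and without a good flag, so no size is given. Leaving out 1 array at a time ended the calls of Klk1c4 (6 of 8 times, and also with median scaling), Pak6 (5) and Olfml2b (7), Pak6 was not called with session as a fixed block (adjusted p = 0.0517), and the count was 20 without SHRSP candesartan replicate 1, 6 with the authors' tables, 8 with only the compared groups in the fit, 22 with session as a random block, 94 with array weights and 4116 with vehicles pooled, which mixes sessions. Within SHRSP (2 arrays against 2), injury genes (adjusted p = 0.0222), matrix genes (0.000101), smooth muscle genes (0.00882) and cell cycle genes (0.0108) fell as lists with an estimated correlation. Within WKY camera called 0 lists (6 at an unadjusted p under 0.05). Tested as a difference between strains, smooth muscle and matrix genes fell more in SHRSP (adjusted p = 0.00744 for both).

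Chlorothiazide (4 arrays against 4 with Solvent B, both strains) changed distal nephron genes. Slc12a3, the target of thiazides, fell by 0.49 ± 0.07 (adjusted p = 0.00233) and by 0.35 ± 0.06 on its other probe (0.0144), and Calb1 fell by 0.73 ± 0.10 (0.000588). Of 13 measured genes of the distal convoluted tubule and divalent ion handling 2 fell and 11 did not pass. The proton pump subunits of intercalated cells Atp6v1g3 and Atp6v1c2 rose by 0.48 ± 0.09 and 0.44 ± 0.08. As lists, the distal convoluted tubule fell (adjusted p = 0.000443 with an estimated correlation) and intercalated cells rose (0.000677), where 1 of 11 list members passed over all probes and 6 rose when adjusted over the list alone. The kallikrein-family genes Klk1c9 and Klk1c4 rose by 1.61 ± 0.14 (adjusted p = 2.39e-06) and 1.23 ± 0.13 (6.71e-05). They belong to a family of near-identical copies, so which members the probes measured is uncertain, and of the kallikrein-kinin list only 1 gene was measured. Dnaaf1 rose by 0.70 ± 0.10, Stap1 by 0.62 ± 0.09 and the transcription factor Hmx2 by 0.55 ± 0.08, while Gp2 fell by 0.62 ± 0.08 and Capn6 by 0.64 ± 0.10. Matrix, macrophage and immediate early lists were lower with the preset correlation only (adjusted p with an estimated correlation = 0.401, 0.198 and 0.401). Limma called 28 probes, 17 up and 11 down. The count was 47 without SHRSP chlorothiazide replicate 1, 15 with only the compared groups in the fit, 54 and 45 with session as a fixed or random block, 109 with array weights and 2907 with vehicles pooled. Atp6v1g3 lost its call whichever array was left out, at a change of at least 0.46, and the second Slc12a3 probe lost it 5 of 8 times, Atp6v1c2 3 of 7 and Capn6 2 of 8.

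Carvedilol (4 arrays against 4 with Solvent C, both strains) raised the fatty acid desaturase Scd by 1.90 ± 0.21 (adjusted p = 0.000168) and lowered interleukin 1 beta (Il1b) by 1.06 ± 0.16 (0.00393) and the vitamin D 24-hydroxylase Cyp24a1 by 0.88 ± 0.17 (0.0263). Scd carried a good flag on 1 of 4 Solvent C arrays and 2 of 4 carvedilol arrays. The cadherin Cdh13 was also called (1.25 ± 0.16, adjusted p = 0.000896), which rests on 1 SHRSP carvedilol array (2.62 in SHRSP), and in WKY the change of -0.12 did not pass. Pspc1 rose by 0.62 ± 0.10, Fbxo36 by 0.47 ± 0.08 and Urah by 0.76 ± 0.15, while Gstz1 fell by 0.22 ± 0.04. When 1 array at a time was left out, Urah lost its call 8 of 8 times and Cyp24a1 and Gstz1 4 of 8. Clock genes (18 measured), immediate early genes (29), macrophage genes (37, of which Il1b fell) and injury genes (22) were lower as lists by camera with the preset correlation only (adjusted p with an estimated correlation = 0.11, 0.397, 0.397 and 0.607). Limma called 37 probes, 25 up and 12 down, of which 19 carried a good flag on more than 20 of the arrays. The count was 67 to 108 when any 1 of the 8 arrays was left out, 8 among probes with a good flag on all 40 arrays, 14 with the authors' tables, 59 without a filter, 92 and 82 with session as a fixed or random block, 4230 with vehicles pooled, and 0 with only the 4 compared groups in the fit (2618 at an unadjusted p under 0.05).

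Averaged over the matched comparisons (14 drug arrays against 14 vehicle arrays), a set chosen after the batches had been seen, Calb1 fell by 0.64 ± 0.06 and Slc12a3 by 0.20 ± 0.04 (-0.11 on its other probe, adjusted p = 0.24), while Klk1c4 rose by 0.78 ± 0.07 and Klk1c9 by 0.77 ± 0.08. Havcr1 fell by 1.75 ± 0.24 on probe GE1278517 (-2.73 in SHRSP, while 0.52 in WKY did not pass). Gpnmb fell by 0.75 ± 0.10, Spp1 by 0.63 ± 0.11 and Col1a1, on a probe other than its list's, by 0.50 ± 0.08. Of 22 injury genes 6 fell, of 38 matrix genes 6, of 37 macrophage genes 1 (Lyz2, -0.24 ± 0.05) and of 33 cell cycle genes 2, with none of these rising. Camera with an estimated correlation called 7 lists lower: matrix (adjusted p = 0.000238), smooth muscle (0.00434), cell cycle (0.00486), injury (0.00594), macrophage (0.00743), distal convoluted tubule (0.00913) and antigen presentation (0.0393). Intercalated cell, proximal tubule, lymphocyte, immediate early and gluconeogenesis lists were called only with the preset correlation (adjusted p with an estimated one = 0.125, 0.102, 0.237, 0.48 and 0.103). The kallikrein-kinin list, with 1 gene measured (0.17), was also called with the preset correlation only. For a single gene no correlation can be estimated, so its second adjusted p of 0.0666 rests on none, and it does not show a change of the set. Counting that single gene as a list, 4 of these lists were higher, among them intercalated cell and proximal tubule, and the lymphocyte list was lower. Limma called 98 probes, 23 up and 75 down, and of 24 named genes 15 kept their call whichever array was left out. Calb1 and Klk1c4 were called for candesartan, chlorothiazide and enalapril in SHRSP alike, as were the unnamed probes GE21429 (3.39, 1.04 and 2.02) and GE14830 (-0.87, -0.85 and -0.83). Candesartan and chlorothiazide, which share no control arrays, had 2 called probes up and 2 down in common, against 0.00408 and 0.00308 for independent lists. Across all probes their changes did not go together (Pearson r -0.0323, Spearman rho -0.0946).

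Injury and matrix genes were then followed by strain. Averaged over the 4 matched drugs in SHRSP, Havcr1 fell by 2.73 ± 0.30 on probe GE1278517 and by 1.56 on probe GE13234 (adjusted p = 5.5e-05 and 0.000345). By drug, the first probe passed for enalapril (-4.61) and candesartan (-3.23, adjusted p = 0.0488), but not for chlorothiazide (-1.56) or carvedilol (-1.53). On this probe the SHRSP vehicle means (n = 2) were 4.872 (H2O), 3.798 (Solvent A), 3.497 (Solvent B) and 2.424 (Solvent C). In the same order the drug means were 0.2607 (enalapril), 0.5719 (candesartan), 1.933 (chlorothiazide) and 0.8928 (carvedilol). Carvedilol was thus compared with the lowest vehicle mean, so the sizes of these changes do not rank the drugs. On the first probe Havcr1 averaged 3.65 ± 1.15 (SD, n = 8) in SHRSP vehicle arrays, 1.13 ± 1.11 (n = 12) in SHRSP arrays of all 6 drugs and 0.52 ± 0.27 (n = 8) in WKY vehicle arrays. On the second it averaged 1.69 ± 0.74, 0.19 ± 0.61 and 2.43 ± 0.37. In WKY, over the 3 matched drugs, the changes of 0.52 and 0.08 did not pass (adjusted p = 1 for both). The difference between the strains was tested over candesartan, chlorothiazide and carvedilol. Matrix genes fell more in SHRSP (mean difference -0.21, adjusted p = 0.00167 with an estimated correlation), as did smooth muscle genes (-0.15, 0.00925). Injury genes passed with the preset correlation, at a mean of -0.33, and not with an estimated one (adjusted p = 0.0558). By drug, camera with an estimated correlation called 2 lists for candesartan. It called 0 for chlorothiazide and 0 for carvedilol (smallest adjusted p = 0.0552 and 0.469, with 6 and 2 lists at an unadjusted p under 0.05). For single genes the difference over these 3 drugs did not pass for Havcr1 (-2.63, adjusted p = 0.15), Lcn2 (-0.72, 0.979), Spp1 (-0.73, 0.768) or Gpnmb (-0.78, 0.574), and 1 probe was called, Ddx24, with the missing values described for candesartan. In the comparisons with H2O it passed for enalapril for Havcr1 (-4.96, adjusted p = 0.00372), Gpnmb (-1.99, 0.00559), Spp1 (-2.15, 0.00627) and Lcn2 (-2.24, 0.0229), for hydralazine for Havcr1 (-4.20, 0.0307) and Gpnmb (-1.83, 0.0254) and for amlodipine for Gpnmb (-1.80, 0.0251). All of these passed with session as a fixed block, and Havcr1, Gpnmb and Spp1 under enalapril kept their call whichever of the 8 arrays was left out, while Lcn2 under enalapril lost it 5 times, Havcr1 under hydralazine 3, and Gpnmb 2 under hydralazine and 3 under amlodipine. Enalapril shared slide series with H2O in SHRSP only, and the 3 drugs were compared with the same H2O arrays, so strain and batch cannot be told apart for enalapril and the 3 results are not independent. Calb1 fell in both strains, by 0.55 ± 0.07 in SHRSP and 0.75 ± 0.08 in WKY.

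**Figure D2:**
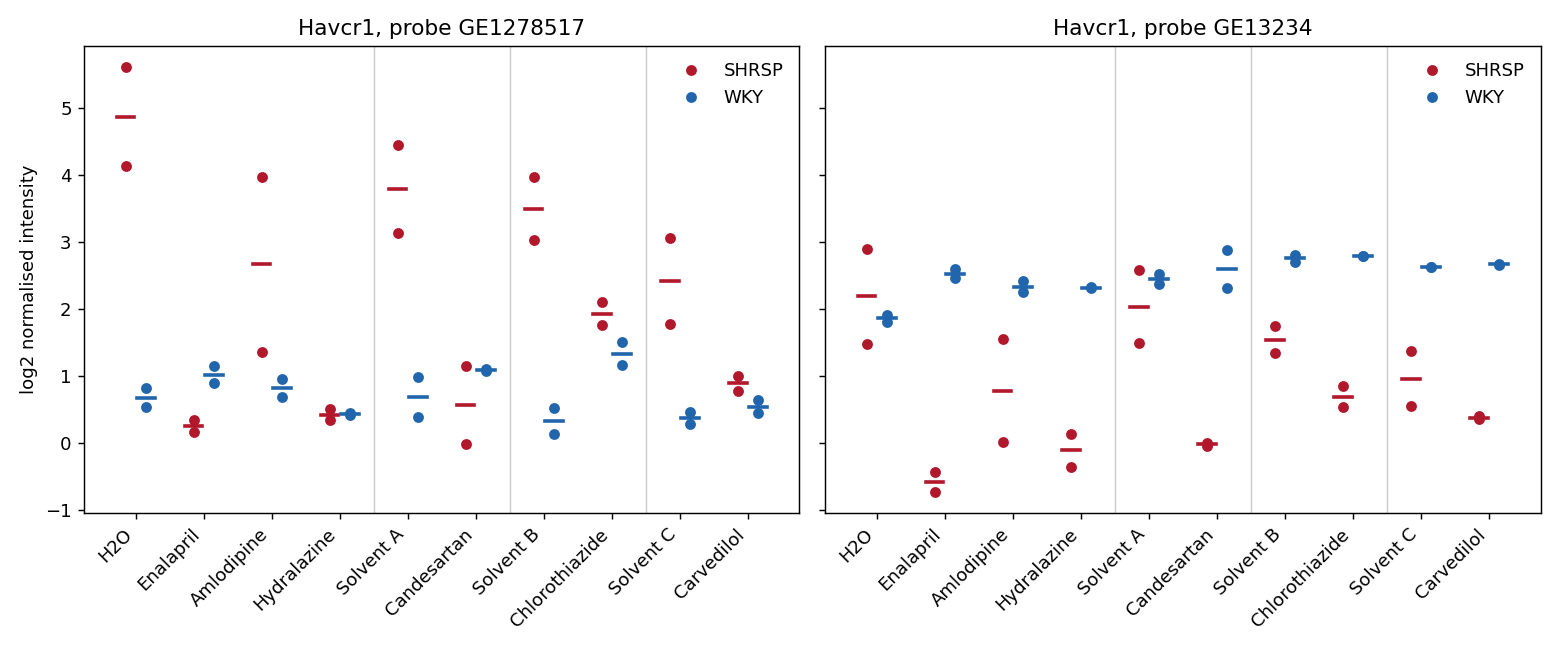
Log2 normalised intensity of Havcr1 on its 2 probes (left GE1278517, right GE13234) in the 10 treatment groups, with red points for SHRSP arrays, blue points for WKY arrays and bars for the mean of 2 arrays. Grey lines part the sets of drugs and the vehicle used for them. On both probes SHRSP arrays of the drugs lie lower on average (1.13 and 0.19) than SHRSP vehicle arrays (3.65 and 1.69), while the order of the strains differs between the probes.

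Enalapril and candesartan act on the same hormonal pathway and have independent controls. In SHRSP, where both are matched, their changes across 24993 probes correlated with a Pearson r of 0.296 (Spearman rho 0.232, covariance 0.00914). Probes are not independent replicates. In the same strain r was 0.0739 for enalapril with chlorothiazide and -0.00868 for enalapril with carvedilol (rho 0.0793 and -0.0241). Matched enalapril minus candesartan called 2 probes by limma, both unnamed. Over both strains 6 were called, but 1 with normexp or the authors' tables, 3 with trend and robust eBayes, 35 without the filter or with session as a fixed block, 6196 with vehicles pooled, 4 to 53 when 1 array was left out and 0 among probes with a good flag on all 40 arrays (900 at an unadjusted p under 0.05). Treh (trehalase, 0.63 ± 0.10) was among the 6, and lost its call with normexp (adjusted p = 0.0839), among probes with a good flag on all arrays (0.0526) and 3 of 16 times when 1 array was left out. The immediate early list was higher with the preset correlation only (adjusted p = 0.773 with an estimated one). Renin-angiotensin blockers against the other 4 drugs gave 449 probes, 148 up and 301 down, a contrast that includes the batch-bound comparisons. The count was 158 with session as a fixed block, 81 with session as a random block, 257 with median scaling, 150 with the authors' tables, 8200 with vehicles pooled and 194 to 907 when 1 array was left out (fewest without SHRSP candesartan replicate 2, most without WKY enalapril replicate 2). Among the genes were Mmp9 (-0.96 ± 0.10), the glucocorticoid-inactivating Hsd11b2 (-0.43 ± 0.05) and the proton pump subunit Atp6v0d2 (-0.34 ± 0.04). Collecting duct principal cell genes (2 of 14 lower, adjusted p = 0.0341 with an estimated correlation) and intercalated cell genes (4 of 11 lower, 0.0255) were lower as lists than under the other 4 drugs. This contrast does not show which side moved, and intercalated cell genes rose under chlorothiazide. Matrix and immediate early lists, 1 of them higher, passed with the preset correlation only (adjusted p with an estimated one = 0.153 and 0.542). Among matched drugs in SHRSP limma called 30 probes, with Hsd11b2 at -0.67 ± 0.09 and Olfml2b at -0.82 ± 0.11, and 0 lists with an estimated correlation (7 at an unadjusted p under 0.05).

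Against H2O, amlodipine gave 7845 probes (3847 up, 3998 down) and hydralazine 7264 (3512 up, 3752 down), over both strains. Drug, scan session and slide series cannot be told apart here. Camera called 0 of 32 lists for either, with 7 and 6 at an unadjusted p under 0.05. Among the genes named by rule were the ribosomal protein gene Rpl13a (1.63 ± 0.11 for amlodipine and 1.51 ± 0.11 for hydralazine) and the transporter Slco1a3 (-1.46 ± 0.17 and -1.21 ± 0.17, the latter not called with session as a fixed block, adjusted p = 0.0773). With scan session as a fixed block, which rests on single WKY enalapril arrays, 1230 and 708 probes passed, and with session as a random block 2132 and 1819. Neither block adjusts for slide series, which amlodipine and hydralazine did not share with H2O, so these counts are not free of batch. Rpl13a also rose by 1.34 under enalapril in WKY (1.44 with the fixed block), where slide series differed from H2O too. For hydralazine 3070 passed with array weights and 1731 with only the compared groups in the fit. Agt, at 0.52 ± 0.18 for amlodipine, was -0.22 with the fixed block, and Nfia and Pakap, at 1.51 ± 0.27 and 1.44 ± 0.20 for hydralazine, were -0.07 each.

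Amlodipine and hydralazine were scanned together in part, so they were compared with each other with session as a block, which called 917 probes, 343 higher and 574 lower with amlodipine. All 4 amlodipine arrays and 1 hydralazine array per strain were in session 2, so this contrast rests mainly on those 2 hydralazine arrays. Without the block 95 passed, and with the session 5 arrays left out 997. Mmp9 was 0.80 ± 0.15 higher with amlodipine, the prostaglandin synthase Ptges 0.51 ± 0.12, Calb1 0.42 ± 0.12 and Dnaaf1 0.77 ± 0.08. Cyp24a1 (-0.71 ± 0.16) and Ccn1 (-1.33 ± 0.24) were lower. For these 6 genes the group means over all arrays ran the same way, but of 42 genes named by rule and past the threshold with the block, the group means of 7 ran the other way, all of them called lower with amlodipine. They were the fatty acid transporter Cd36 (-0.85 ± 0.17 with the block, means of 0.54 with amlodipine and 0.43 with hydralazine), Gatm (-0.41, 5.22 and 4.75), Glud1 (-0.64, 3.14 and 2.97), Canx (-0.41, 2.89 and 2.72), Ndrg1 (-1.18, 1.04 and 0.96), Mtmr6 (-1.13, 0.66 and 0.64) and Oxsr1 (-0.71, -0.34 and -0.35), so their direction depends on the block. Of the lists, thick ascending limb genes were lower with the preset correlation only (adjusted p = 0.636 with an estimated one).

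The mean of all 6 drugs called 3966 probes, 2127 up and 1839 down, which includes the batch-bound comparisons, and 766 with session as a fixed block, 1370 with session as a random block and 1726 with vehicles pooled. Klk1c4 rose by 0.71 ± 0.07, Havcr1 fell by 1.31 ± 0.21 and Slc12a3 by 0.23 ± 0.04 (-0.08 on its other probe, adjusted p = 0.0825). With session as a fixed block Havcr1 was -1.25 and no longer passed (adjusted p = 0.119). Of the lists, 6 passed with the preset correlation and 0 with an estimated one (smallest adjusted p = 0.154, 4 at an unadjusted p under 0.05). The moderated F test of drug by strain called 183 probes, but 85 with normexp, 112 with median scaling, 65 with the authors' tables, 83 among probes with a good flag on all arrays, 285 with session as a random block, 313 with vehicles pooled and 104 to 401 when 1 array was left out (fewest without WKY enalapril replicate 2, most without WKY enalapril replicate 1), and 9 of 100 drawn splits called as many. The 4 vehicles differed at 12886 probes by the F test and at 830 with session as a random block, and vehicle and scan session cannot be told apart.

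Whether the drugs moved the strain difference back toward WKY was asked last. The median change in SHRSP of the higher genes minus that of the lower genes, chosen on vehicles outside each comparison, was -0.03 for enalapril, -0.03 for candesartan, -0.04 for chlorothiazide and -0.05 for carvedilol. In WKY the same 4 values were -0.01, 0.00, 0.03 and 0.00. The mean over matched drugs was -0.04 in SHRSP (4 drugs) and 0.01 in WKY (3 drugs), and the difference between the strains was not tested. For these 4 drugs in SHRSP, the smallest adjusted p of the rotation test fry, which asks whether a set moves on balance one way, was 0.0531. For the batch-bound drugs the values were -0.08 (amlodipine) and -0.09 (hydralazine) in SHRSP and -0.06 and -0.09 in WKY. The mean over all 6 drugs in SHRSP was -0.05, and -0.11 with vehicles pooled. With pooling, the vehicle arrays on which the genes were chosen are also in the comparison. The value of -0.11 is therefore not independent of that choice.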

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

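The 3 tests on tubular injury genes were chosen after the result was seen, as were the comparisons limited to drugs that share scan session and slide series with their vehicle. Drug effects that differed between SHRSP and WKY, by limma's test of the difference itself, come first. For candesartan 4 probes differed, including Ddx24 (-4.40), Nrf1 (-0.56) and Rbx1 (-8.95), and for chlorothiazide 1. For carvedilol 17 differed, including Cdh13 (2.74), C1ql3 (0.54), Kcns1 (0.47), Adal (0.89) and Fibin (-1.19). With session as a fixed block Nrf1 (adjusted p = 0.0892), Rbx1 (0.0996) and Fibin (0.0542) were not called. These are fitted differences. Ddx24, Rbx1, C1ql3 and Kcns1 had no good flag on 1 side, Ddx24, Rbx1 and Cdh13 lacked values, and Cdh13 rests on 1 SHRSP carvedilol array, so for these genes the size was not measured.

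For enalapril 707 probes differed between strains, including Fgd4 (0.93, on the floor in WKY with enalapril, so its size was not measured), Tmem43 (-1.89), Tbc1d1 (1.03), Scara3 (-1.32) and Cpb1 (0.78, with no good flag on 1 side, so its size was not measured). Enalapril shares slide series with H2O in SHRSP and not in WKY, so strain and batch cannot be told apart there. For amlodipine 99 differed, including Myh9 (-1.36), Mtres1 (1.24), Nrep (-1.32), Olfml2b (-1.12) and Ldha (1.39). For hydralazine 93 differed, including Mtres1 (1.46), Myh9 (-1.23), Spg11 (-1.37), Tmem43 (-1.27) and Col15a1 (-1.02). Both drugs were compared with the same H2O arrays, so their shared genes are not independent.

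Other splits of the same arrays were counted, the real split included, in fits made for this test. For candesartan 1 of 34 splits called as many probes as the real one (2, highest other 1) and for chlorothiazide 1 of 34 (8, highest other 2). That is the lowest rank these splits can give, and they also exchange arrays between the strains. The counts are small and not those of the fit to all arrays, so chance was not excluded for the probes called there. For carvedilol 1 of 34 did (3, highest other 1), with strain and drug as separate terms, while 1 mean per group on the same 8 arrays called 0, so for its 37 probes chance was not excluded. For amlodipine it was 1 of 34 (5614, highest other 1), for hydralazine 1 of 34 (2093, highest other 0) and for amlodipine against hydralazine 1 of 34 (11, highest other 3). The last of these fits held strain and session, and its 11 probes are not the 917 of the fit to all arrays. For enalapril over both strains 34 of 34 splits called as many (highest other 1), because the real split called 0 in this fit of 8 arrays. The count therefore says nothing about the 523 probes of the fit to all arrays, for which chance was not excluded. For strain it was 1 of 100 drawn splits (5626, highest other 2535), for vehicle differences 1 of 100 (12592, highest other 5398) and for renin-angiotensin blockers against other drugs 1 of 100 (444, highest other 76). For the mean of 6 drugs 2 of 100 called as many (3861, highest other 3905). For enalapril minus candesartan 12 of 100 did (4, highest other 1900) and for drug by strain 9 of 100 (178, highest other 2073), so chance cannot be excluded for these 2, and splits with several times the real count point to a structure of the arrays. Excluding chance does not exclude batch for amlodipine, hydralazine, vehicles, renin-angiotensin blockers against other drugs or the mean of 6 drugs. For the last 2, labels were permuted among H2O, enalapril, amlodipine and hydralazine arrays, which differ in session and slide series. The real labels largely follow these batches, so the ranks cannot tell drug from batch.

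The many probes called for amlodipine and hydralazine against H2O were weighed first. A response shared with drugs that have a vehicle in their session could not be decided and stays open. The r across probes with the mean change under candesartan, chlorothiazide and carvedilol averaged -0.158 (-0.168 to -0.147). The changes under these drugs barely went together across probes (pairwise Pearson r -0.0323, 0.0303 and 0.0943). Their mean is therefore a poor measure of a shared response. Scan session and slide series may account for much of the change against H2O. The r with the change of Solvents B and C from other H2O arrays averaged 0.679 (0.637 to 0.72), which could also hide a shared part. Solvents B and C also differ from H2O as vehicles, and an effect of either drug of its own stays open.

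Strain differences of at least 8-fold were weighed next. A sequence variant under the probe in 1 strain may explain many of them: in the 14 genes with another probe, the median ratio of the other probe's difference to the first's was 0.0257 (bootstrap interval -0.00444 to 0.0977). The ratio was at most 0.2 in 11 genes and at least 0.5 in 1, Ucp1, which was lower in SHRSP on both probes (-4.10 and -2.93). First probes were chosen for large differences, which lowers such ratios, and among genes with log2 differences of 0.5 to 1 the median ratio was 0.357. Probes of different transcripts, and real strain differences in genes without another probe, stay open.

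Lower tubular injury genes in treated SHRSP were weighed last. A single diverging array is argued against as the whole cause, since the list's mean change over the matched drugs was -0.41 and at its smallest -0.34, without SHRSP H2O replicate 2. A different share of medulla is argued against too as the whole cause, since the medulla list changed by -0.13 (SE 0.0506) where the injury list changed by -0.41 (SE 0.0894). These SEs run over the genes of a list and not over arrays. The medulla list fell as well, so a part of the change due to medulla stays open. A response of the hypertensive strain may be involved and stays open, because the change in SHRSP minus that in WKY was -0.33 with an adjusted p of 0.0558 at an estimated correlation. Blood pressure was not part of the values used here.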

How the results depend on the processing

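The limits to the matched sets, amlodipine minus hydralazine and leaving out POOR spots were chosen after seeing the data, and the cause was not tested for values below unless given. The array number limits precision, and 59.3% to 72.6% of probes per array had a good flag. No paired analysis was possible because the labels carry no replicate numbers. Counts were within 1.5 times of those reported except as follows, where each value is the number of probes called.

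With normexp, enalapril minus candesartan gave 1 and drug by strain 85. With median scaling, renin-angiotensin blockers against others gave 257 and drug by strain 112. With the authors' tables, candesartan gave 6, carvedilol 14, renin-angiotensin blockers 150, enalapril minus candesartan 1 and drug by strain 65. Without a filter, carvedilol gave 59 and enalapril minus candesartan 35. With a good flag on all 40 arrays, which tests 14054 probes, strain gave 3574, carvedilol 8, drug by strain 83 and enalapril minus candesartan 0 by limma (900 at an unadjusted p under 0.05). With session as a fixed block, enalapril gave 892, chlorothiazide 54, carvedilol 92, amlodipine 1230, hydralazine 708, the 6-drug mean 766, renin-angiotensin blockers 158 and enalapril minus candesartan 35. That block does not adjust for slide series. With session as a random block, candesartan gave 22, chlorothiazide 45, carvedilol 82, amlodipine 2132, hydralazine 1819, the 6-drug mean 1370, renin-angiotensin blockers 81, drug by strain 285 and vehicles 830. With trend and robust eBayes, enalapril minus candesartan gave 3. With array weights, enalapril gave 44, candesartan 94, chlorothiazide 109 and hydralazine 3070. With vehicles pooled, which mixes sessions, enalapril gave 1560, candesartan 4116, chlorothiazide 2907 and carvedilol 4230. The 6-drug mean then gave 1726, renin-angiotensin blockers 8200, enalapril minus candesartan 6196 and drug by strain 313. The mean reversal value over the 6 drugs, -0.05 as reported, was -0.11 with vehicles pooled. Its genes were chosen on vehicle arrays that then enter the comparison, so this value is not independent of the choice. With only the compared groups in the fit, candesartan gave 8, chlorothiazide 15, hydralazine 1731, enalapril 0 (3057 at an unadjusted p under 0.05) and carvedilol 0 (2618). With only arrays whose vehicle shares session and slide series, candesartan gave 21, chlorothiazide 69 and carvedilol 118. The matched sets gave 245 for enalapril, 98 for the drug mean, 30 for renin-angiotensin blockers and 2 for enalapril minus candesartan, and amlodipine minus hydralazine gave 917.

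Leaving out 1 array leaves a lone array that is assumed to vary like the other groups. Counts then ran from 4703 to 5306 for strain, 206 to 783 for enalapril, 9 to 20 for candesartan, 20 to 47 for chlorothiazide, 67 to 108 for carvedilol, 6229 to 7148 for amlodipine, 5643 to 8163 for hydralazine, 2722 to 4746 for the 6-drug mean, 194 to 907 for renin-angiotensin blockers, 4 to 53 for enalapril minus candesartan, 104 to 401 for drug by strain and 11391 to 12150 for vehicles, and the reversal value from -0.06 to -0.04. Enalapril gave 206 without SHRSP H2O replicate 2, 249 without WKY H2O replicate 1 and 330 without WKY enalapril replicate 2, and renin-angiotensin blockers 194 without SHRSP candesartan replicate 2 and 907 without WKY enalapril replicate 2. For carvedilol the probes gained had differed between the replicates of the group left with 1 array (median 0.42 to 0.53, against 0.10 to 0.11 for all probes).

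With session as a fixed block Agt under amlodipine was -0.22, and under hydralazine Nfia was -0.0746 and Pakap -0.0728. The gluconeogenesis list under enalapril in SHRSP was -0.00214 with vehicles pooled. Adra2a on probe GE22056 was 0 for amlodipine minus hydralazine with POOR spots left out. The share of calls that were higher moved with scaling. It was 57.2% for enalapril (77.9% with median scaling, 82.7% with the authors' tables), 46.2% for candesartan (30%, 16.7%), 60.7% for chlorothiazide (70.8% with median scaling), 67.6% for carvedilol (50% with the authors' tables) and 53.6% for the 6-drug mean (64.3%, 68.9%). For enalapril minus candesartan it was 33.3% (62.5%, 100%, and 0% with normexp). Klk1c4 under candesartan had an adjusted p of 0.103 with median scaling and 0.15 with the authors' tables, in a range of 6.99e-05 to 0.15 over its alternatives other than leaving out arrays, where it reached 0.276.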

Other observations

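The changes under enalapril and candesartan within SHRSP were compared with 99 draws of permuted treatment labels, a test chosen after the correlation was seen. Over probes with a value on every array the real Pearson r was 0.305, the permuted ones ran from -0.328 to 0.366, and 2 of the 99 were as high. Labels were permuted within strain among a vehicle and all drugs set against it. H2O and enalapril arrays were thus exchanged with amlodipine and hydralazine arrays of other sessions and slide series. Permuted enalapril changes therefore held batch differences that the matched change lacks, so the draws cannot decide whether the real r exceeds chance. The unnamed probe GE21429 rose under candesartan (3.39), enalapril in SHRSP (2.02) and chlorothiazide (1.04).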
